A study of Chlamydomonas reinhardtii with 2 samples.

How the data were processed

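RNA sequencing libraries from 2 cultures of Chlamydomonas reinhardtii strain 21gr, a wild-type strain also known as CC-1690, were compared. Per the labels' protocols, cells were kept in continuous light of 70 µmol per square metre and second at 25 °C with shaking at 200 rpm. They were then held for 24 h in acetate medium with 1.1 mM phosphate (phosphate replete) or without added phosphate (phosphate deprived). Total RNA was extracted with phenol and chloroform and sequenced as Illumina libraries, per the labels' protocols. Each condition had 1 library, so the groups were taken directly from the labels and each table column was matched to its library by the library code in the labels.

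The authors deposited RPKM values, reads scaled to transcript length and library depth, for 17147 gene loci in both libraries. Bowtie is named per the submitters' processing notes, with no version. The counting method, the genome build, the annotation version and any filter are not given in the sources used here, and no coordinates are printed for that reason. How reads of near-identical gene copies or of overlapping genes were counted is likewise not given, so values of close paralogs such as neighbouring PTB transporter genes are uncertain to that extent. Gene symbols and descriptions are those of the deposited table, in which 3231 loci have a symbol. The reference table of assembly Chlamydomonas_reinhardtii_v5.5 added none.

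The deposited values contain no 0. A ratio of 0.870 between the deprived and the replete value was shared to 6 digits by 1249 genes, and 1153 of the 1153 of these that allowed the test had values that divided the highest of them, 160.7 RPKM in the replete library, into a whole number (tolerance at most 0.02). The same held for 372 of 15753 other genes. These values have the pattern of a fixed count added to every gene before scaling, with the whole quotient read as a length in bases. At a number of loci that length would be only a few bases, down to 1 base, so what the quotient stands for there is open. No source used here states such a step, so it is an inference from the values. Next to the shared ratio, 55 genes lay at 1.496 times and 56 genes at 1.504 times that ratio (tolerance 0.001), the pattern of a count of 1 added in each of 2 runs per library. Under that reading, the added count is worth 0.161 RPKM in the replete and 0.140 RPKM in the deprived library at a length of 1000 bases. About 10.4 and 12.3 reads then lie behind 1 RPKM, and 122 and 141 reads behind 10 RPKM, at that length. Limits for genes without reads were computed from 3 counts per library and cover counting error only.

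The fold of each gene was computed as log2 of the deprived over the replete value after adding a pseudocount of 1 RPKM to both, a scale that understates differences of weakly expressed genes. Genes with a mean RPKM of at least 1 over both libraries entered the counts, 13855 in all. Genes at least 2-fold and at least 4-fold higher or lower were counted by size alone. No test across samples was possible with 1 library per condition, and no p-value is given. Gene lists were defined by patterns on gene symbols and descriptions before the data were examined. For each of the 27 lists with at least 3 measured members, the median fold was placed among those of 10000 random lists of the same size matched on mean expression in 20 bins. A list outside the central 95% of the random lists is called above or below them. This percentile describes these 2 libraries and not the conditions.

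Named genes were chosen by a rule written before the data were examined. It takes the 12 highest and 12 lowest folds among genes with a symbol, a mean RPKM of at least 1 and a larger RPKM of at least 10. It adds the 3 members of each list with the largest absolute fold, and every member at least 4-fold different where these are 6 or fewer. It also names PSR1, PHOX, the PTB and PTA genes, SQD1, SQD2, ARS1, ARS2, LHCBM9 and PNP1 wherever measured; SQD2 and PNP1 matched no symbol. Some list members do not do what the list name says, such as PAP genes described as poly(A) polymerases and AOT genes described as amino acid transporters, and medians without them were computed as well.

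The alternatives tried were pseudocounts of 0.1 and 5 RPKM, scaling to the same median, trimmed mean scaling (30% trimmed on the log ratio and 5% on the mean), scaling to a common sum, quantile normalization, no filter, a mean RPKM of at least 5, and list members matched by symbol alone. After the data were seen, a fold without pseudocount, lists without misfitting members and the removal of genes at the shared ratio were added. The calculations were tested on simulated libraries of 17147 genes for the deprived against replete comparison. Of 100 genes raised 8-fold, 100 were found at least 4-fold higher, and of 100 lowered 8-fold, 99 were found at least 4-fold lower, with 0 other genes in either count. The simulated spread was narrower than that of the data and held no counting error and no floor. The changed genes were drawn from well-expressed genes only. The simulation therefore checks the calculation and gives no rate of false calls in these libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.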

Results

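Gene expression was measured by RNA sequencing in Chlamydomonas reinhardtii, a unicellular green alga, after 24 h with 1.1 mM phosphate or without added phosphate. Each condition was represented by 1 library, so there are no replicates, no value below has a replicate error, and differences are between these 2 libraries. RPKM values summed to 901012 in the replete and 855498 in the deprived library, and the 10 highest genes held 16.6% and 16.5% of these sums. Across genes, which are not independent replicates, log2 values of the libraries correlated with Pearson's r of 0.952 and Spearman's rho of 0.925.

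The comparison asks which transcripts differ in abundance when phosphate is withheld. Genes for phosphate uptake and for release of phosphate from organic compounds were among those most strongly higher in the deprived library. PHO1, an alkaline phosphatase gene (Cre08.g359300), had 0.529 RPKM in the replete and 198 RPKM in the deprived library, a log2 fold of 7.02. PTB6a, a sodium/phosphate symporter gene, had 3.22 and 338 RPKM (log2 fold 6.33). The lowest fold among genes with a symbol was that of PTA1, a proton/phosphate symporter gene, with 28.4 RPKM in the replete and 0.582 RPKM in the deprived library (log2 fold -4.22). Plastid ribosomal protein genes were lower as a group, with all 29 measured members below 0.

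Of 13855 genes with a mean RPKM of at least 1, 775 (5.59%) were at least 2-fold higher and 227 (1.64%) at least 2-fold lower in the deprived library, and 12853 (92.8%) lay within 2-fold. The genes within 2-fold include 405 at the shared ratio of 0.870, which have the pattern of genes without reads in both libraries. These 405 also entered the correlations above. At least 4-fold higher were 143 genes and at least 4-fold lower were 7. The 7 lower genes were PTA1, PTA3, FEA1, ADK4 and, outside the naming rule and chosen after their values were seen, Cre09.g403500, Cre09.g403450 and Cre12.g546600. The median log2 fold over all these genes was 0.14, and the split depended on scaling. Higher genes made up 77.3% of the genes at least 2-fold different as deposited, against 53.8% (513 higher and 440 lower) after scaling to the same median, 57.7% (542 and 397) after trimmed mean scaling, 56.4% (512 and 395) after quantile normalization and 83.3% (943 and 189) after scaling to a common sum. The first 3 of these scalings lowered the median fold, by 0.17, 0.14 and 0.17, and the common sum moved it the other way, to 0.21, while the list comparisons below are relative to other genes of these libraries.

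**Figure D1:**
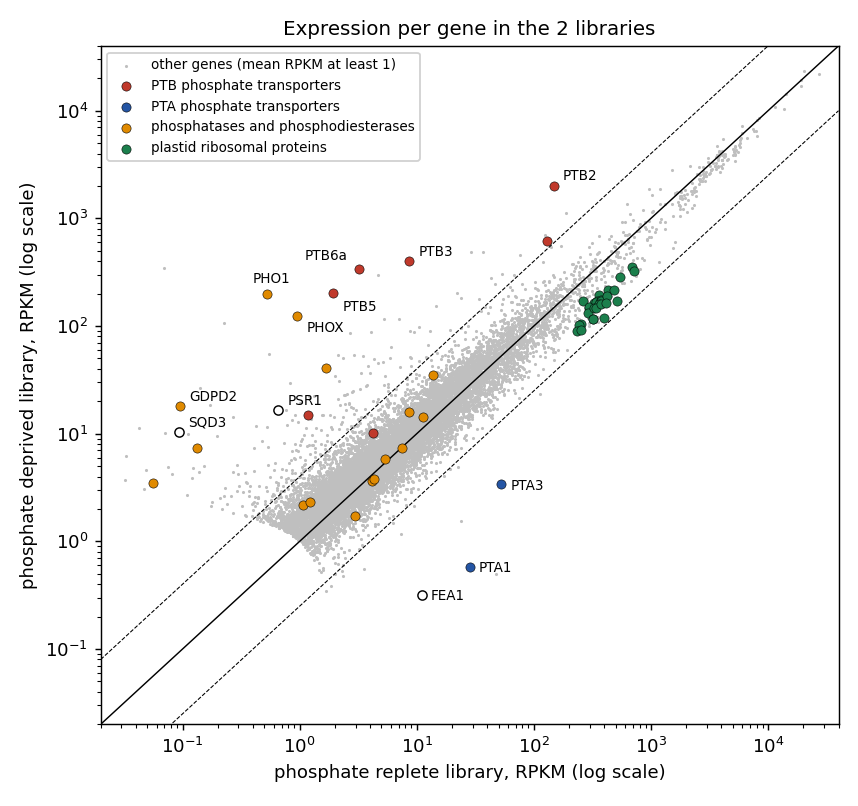
RPKM of each gene with a mean RPKM of at least 1 in the replete library (x axis, log scale) against the deprived library (y axis, log scale); the solid line marks equal values and the dashed lines a 4-fold ratio, and open circles are PSR1, SQD3 and FEA1. The 7 PTB transporters plotted lie above the solid line and the 2 PTA transporters plotted below it, with PTA1 at 28.4 and 0.582 RPKM; some values at the low end have the pattern of genes without reads.

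All 7 measured PTB genes, coding for sodium/phosphate symporters, were at least 2-fold higher in the deprived library, with a median log2 fold of 3.76 that 0 of 10000 matched random lists reached. PTB5 had 1.94 RPKM in the replete and 201 RPKM in the deprived library (log2 fold 6.11), and PTB3 had 8.66 and 399 RPKM (5.37). PTB2, the most abundant of these, had 148 and 2016 RPKM (3.76). PTB4 had 130 and 616 RPKM, PTB8 had 1.19 and 14.9 RPKM, and PTB7 had 4.20 and 10.2 RPKM. PTB9 stayed below the filter, with 0.498 and 0.496 RPKM. The PTA genes code for proton/phosphate symporters, and both measured members, too few for a list comparison, were lower. PTA3 had 52.8 RPKM in the replete and 3.38 RPKM in the deprived library (log2 fold -3.62), and PTA4 was below the filter with 0.0916 and 0.832 RPKM.

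Among 16 genes for phosphatases and phosphodiesterases, 7 were at least 2-fold higher and 0 lower, with a median log2 fold of 0.71 (percentile 99.98). Without members described as something else, such as poly(A) polymerases, a removal chosen after the data were seen, the median was 2.10. PHOX, a phosphate-repressible alkaline phosphatase gene (Cre04.g216700), had 0.953 RPKM in the replete and 124 RPKM in the deprived library (log2 fold 5.995). The metallophosphoesterase gene MPA1 had 1.67 and 40.9 RPKM (3.97), and the alkaline phosphatase gene PHOD had 0.0556 and 3.51 RPKM (2.10), with a replete value that is also within rounding of that of a gene without reads. The neighbouring genes GDPD1 and GDPD2 code for glycerophosphodiester phosphodiesterases, enzymes that split deacylated phospholipids. Their replete values had the pattern of genes without reads, an inference from the table's values, and against a limit of 3 counts they were at least 36.9-fold and at least 125-fold higher in the deprived library, where they had 7.41 and 18.01 RPKM.

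Of 9 genes for phosphate sensing, polyphosphate and SPX proteins, 3 were at least 2-fold higher and 0 lower (median log2 fold 0.60, percentile 98.7). PSR1, the transcriptional regulator of the phosphorus starvation response, had 0.659 RPKM in the replete and 16.4 RPKM in the deprived library (3.39). LPB1 had 8.26 and 18.6 RPKM (1.08), and VTC1, a vacuolar transport chaperone gene, had 42.9 and 90.0 RPKM (1.05). With a pseudocount of 5 RPKM the median of this list was 0.30 and lay within the range of random lists.

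**Figure D2:**
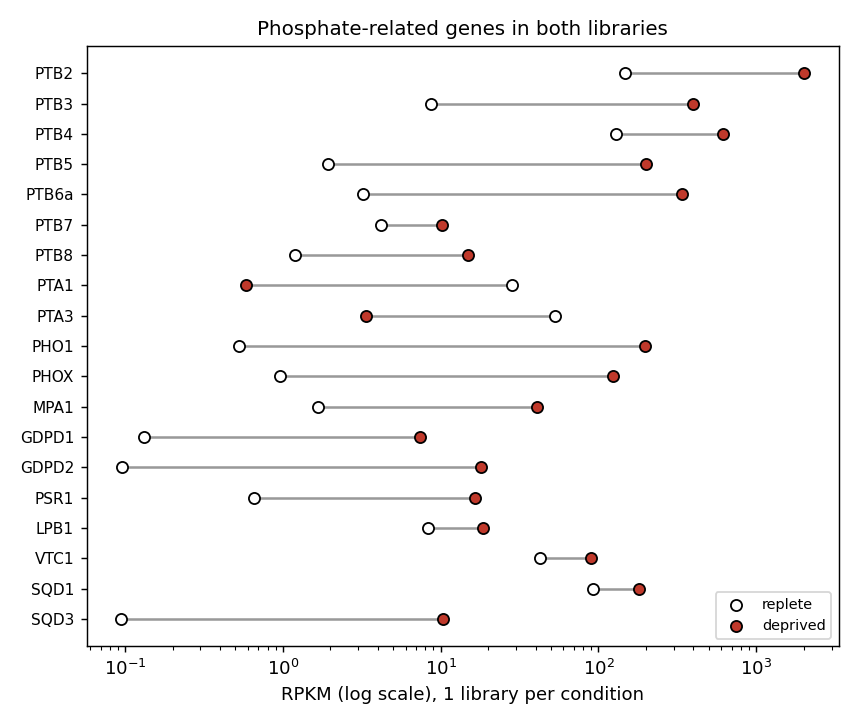
RPKM (x axis, log scale) of phosphate-related genes in the replete library (open circles) and the deprived library (red circles), 1 library per condition. PTB2 extends from 148 to 2016 RPKM, whereas PTA1 and PTA3 have their deprived value to the left of the replete value; the replete values of GDPD1, GDPD2 and SQD3 have the pattern of genes without reads.

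The sulfolipid and galactolipid genes had a median log2 fold of 0.96 over 3 members (percentile 98.6). SQD3, a sulfolipid synthase gene with the same pattern in the replete library, was at least 73.1-fold higher in the deprived library at 10.4 RPKM. SQD1, coding for UDP-sulfoquinovose synthase, had 92.5 and 181 RPKM (0.96), and the galactolipid galactosyltransferase gene DGD1 had 18.2 and 24.6 RPKM (0.41). Genes for phospholipid and betaine lipid synthesis lay within the range of random lists, with 1 of 12 at least 2-fold higher and a median of 0.18 that turned below 0 after scaling to the same median. In this list the serine decarboxylase gene SDC1 had 108 and 218 RPKM (1.01), the glycerol-3-phosphate acyltransferase gene PLSB1 had 44.3 and 22.7 RPKM (-0.93), and the phosphatidylinositol synthase gene PIS1 had 10.7 and 16.0 RPKM (0.54). For triacylglycerol synthesis 2 genes were measured, too few for a list comparison, and neither was 2-fold different.

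Plastid ribosomal protein genes had a median log2 fold of -1.15, with 21 of 29 at least 2-fold lower and 0 of 10000 random lists as low. PRPS6 had 399 RPKM in the replete and 119 RPKM in the deprived library (-1.74), PRPL29 had 517 and 171 RPKM (-1.59), and PRPL1 had 319 and 116 RPKM (-1.46). PRPL7/L12 (1181 and 395 RPKM, -1.58) and PSRP-3 (294 and 99.8 RPKM, -1.55) are further plastid ribosomal protein genes, which the list pattern did not match. All 29 members stayed below 0 under each of the 4 scalings tried. The highest of them had -0.62 as deposited, further from 0 than the scalings moved the median fold over all genes. Those at least 2-fold lower numbered 28 after scaling to the same median and after trimmed mean scaling, 21 after quantile normalization and 19 after scaling to a common sum. Cytosolic ribosomal protein genes had a median of -0.23 (percentile 1.05), with 51 of 60 below 0 (35 after quantile normalization) and 0 at least 2-fold different. RPS24, RPS26 and RPL14 had log2 folds of -0.55, -0.48 and -0.40. The median of this list was -0.04 after quantile normalization, and there, as with a mean RPKM of at least 5, it lay within the range of random lists.

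Genes of chlorophyll synthesis had a median log2 fold of -0.42 with 21 of 27 below 0, and 0 of 10000 random lists were as low. No member was 2-fold different in the deposited values with the pseudocount of 1 RPKM. After scaling to the same median CHLD and CHLG were at least 2-fold lower, and without a pseudocount CHLD was at least 2-fold lower and GTR6, described as a glycosyl transferase, at least 2-fold higher. CHLD, coding for a magnesium chelatase subunit, had 69.0 RPKM in the replete and 34.4 RPKM in the deprived library (-0.98). Chlorophyll synthetase (CHLG) had 87.7 and 48.0 RPKM (-0.86), and glutamate-1-semialdehyde aminotransferase (GSA) had 195 and 116 RPKM (-0.75). The glyoxylate cycle and acetate use genes were below the random lists as well (median -0.58, percentile 0.42), with 3 of 10 at least 2-fold lower and 0 higher. Isocitrate lyase (ICL1) had 1593 and 607 RPKM (-1.39), malate synthase (MAS1) had 681 and 261 RPKM (-1.38), and acetyl-CoA synthetase (ACS3) had 744 and 292 RPKM (-1.35).

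Flagellar and intraflagellar transport genes had a median log2 fold of 0.51, above all 10000 random lists, with 265 of 284 above 0, 5 at least 2-fold higher and 1 at least 2-fold lower. Members below 0 numbered 19 as deposited, 48 after scaling to the same median, 44 after trimmed mean scaling, 41 after quantile normalization and 18 after scaling to a common sum. The flagellar associated protein genes FAP199 (4.70 and 45.7 RPKM, 3.03), FAP172 (11.9 and 3.84 RPKM, -1.42) and FAP138 (24.5 and 60.2 RPKM, 1.27) had the largest absolute folds. DNA replication and cell cycle genes had a median of 0.57, which no random list reached, with 39 of 41 above 0 (37 after scaling to the same median) and 5 at least 2-fold higher, against 13 without a pseudocount and 0 with 5 RPKM. The D-type cyclin gene CYCD4 had 0.520 and 3.23 RPKM (1.47), the replication helicase subunit gene MCM4 had 2.59 and 7.44 RPKM (1.23), and the ribonucleotide reductase gene RIR1 had 13.4 and 31.7 RPKM (1.18).

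The carbon-concentrating mechanism list lay above the random lists (median 0.40, percentile 99.5), with 7 of 32 at least 2-fold higher and 1 lower. CCP2, a low-CO2-inducible chloroplast envelope protein gene, had 5.30 and 28.4 RPKM (2.22), and the low-CO2-inducible genes LCI31 (8.87 and 42.7 RPKM) and LCI30 (119 and 395 RPKM) had log2 folds of 2.14 and 1.72. Autophagy and proteolysis genes had a median of 0.35 (percentile 98.7), with 3 of 42 at least 2-fold higher and 0 lower. The autophagy genes APG7 (3.32 and 8.26 RPKM) and APG8 (74.5 and 159 RPKM) had log2 folds of 1.10 and 1.08, and the cysteine endopeptidase gene CEP1 (145 and 295 RPKM) had 1.02. Fermentation and hydrogenase genes had a median of 0.47 (percentile 98.4), with 2 of 14 at least 2-fold higher and 0 lower. Here pyruvate-ferredoxin oxidoreductase (PFR1) had 1.34 and 6.82 RPKM (1.74), acetate kinase (ACK1) had 24.2 and 55.0 RPKM (1.15), and pyruvate-formate lyase (PFL1) had 357 and 689 RPKM (0.95).

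Cell wall and gametogenesis genes had a median of 0.33 (percentile 97.8), with 7 of 34 at least 2-fold higher and 1 lower. The pherophorin gene PHC24 had 9.56 and 88.2 RPKM (3.08), NSG13 had 2.45 and 18.8 RPKM (2.52), and the fasciclin-like gene FAS2 had 5.54 and 21.2 RPKM (1.76). The autophagy list lay within the range of random lists with a mean RPKM of at least 5, the fermentation list without pyruvate dehydrogenase members, and the cell wall list without genes at the shared ratio.

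**Figure D3:**
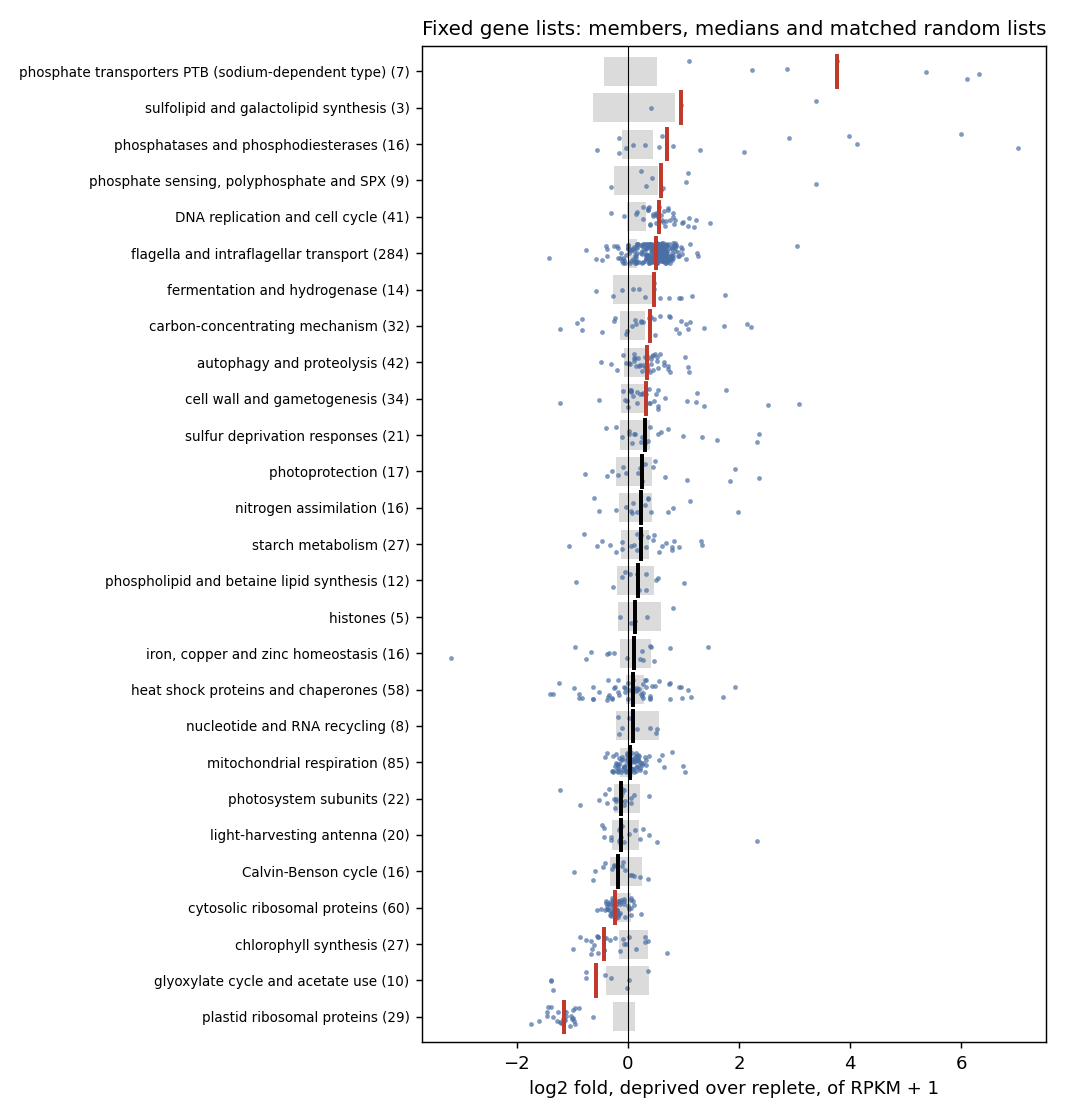
Log2 fold of deprived over replete RPKM (x axis) of each measured member (blue points) of the fixed gene lists, with the number of members in parentheses. Vertical bars are list medians, red where outside the central 95% of matched random lists (grey bands); the median of plastid ribosomal proteins is -1.15 and that of PTB transporters 3.76. The medians of phospholipid synthesis, antenna, Calvin-Benson cycle, metal homeostasis, histones, heat shock, mitochondrial respiration and nucleotide recycling change sign under at least 1 scaling.

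In the sulfur deprivation list, 4 of 21 genes were at least 2-fold higher and 0 lower, and the median of 0.31 lay within the range of random lists (percentile 89.9). The sodium/sulfate co-transporter gene SLT1 had 1.98 and 14.2 RPKM (2.36), and LHCBM9, a light-harvesting protein gene also counted in the antenna list, had 2.76 and 17.8 RPKM (2.32). The extracellular polypeptide gene ECP76 had 0.291 and 2.93 RPKM (1.61), and the arylsulfatase gene ARS1 had 0.418 and 2.59 RPKM (1.34). ARS2 was below the filter with 0.483 and 0.540 RPKM. Nitrogen assimilation genes had a median of 0.24 (percentile 79.8), with 2 of 16 at least 2-fold higher and 0 lower. Nitrite reductase (NII1) had 0.405 and 4.53 RPKM (1.98), and glutamate dehydrogenase (GDH1) had 17.1 and 30.8 RPKM (0.81). NAR1.2, also counted among the at least 2-fold higher genes of the carbon-concentrating list, had 41.9 and 92.5 RPKM (1.13).

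Light-harvesting antenna genes lay within the range of random lists, with a median of -0.13 and a mean of 0.04, 1 of 20 at least 2-fold higher and 0 lower, and a median above 0 after quantile normalization. Apart from LHCBM9, the largest absolute folds were those of LHCBM5 (2147 and 3081 RPKM, 0.52) and LHCA3 (1780 and 1297 RPKM, -0.46). Photosystem subunit genes had a median of -0.13, with 1 of 22 at least 2-fold lower, PSBP6 (81.6 and 34.3 RPKM, -1.23), while PSBP4 and PSAN had -0.87 and -0.53. Calvin-Benson cycle genes had a median of -0.18, just above 0 after quantile normalization, and none of 16 was 2-fold different as deposited; RPI1, RPE1 and GAP3 had -0.97, -0.63 and -0.60, and RPI1 was at least 2-fold lower after scaling to the same median. Photoprotection genes had a median of 0.26 (percentile 83.3), with 4 of 17 at least 2-fold higher and none of the 17 lower. LHCSR1, a stress-related chlorophyll a/b binding protein gene, had 34.0 and 179 RPKM (2.36), the plastid alternative oxidase gene PTOX1 had 8.68 and 36.0 RPKM (1.94), and the early light-inducible protein gene ELI4 had 8.25 and 32.2 RPKM (1.85). The gene annotated as LHCSR2 or LHCSR3.1 (Cre08.g367500, 124 and 694 RPKM, 2.48) and the early light-inducible gene ELI2-1 (219 and 89.4 RPKM, -1.28) are of the same kinds but were not matched by the list pattern, and so are left out of its median and counts; both lie outside the range of the list.

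Iron, copper and zinc homeostasis genes had a median of 0.11 and a mean of -0.14, with 1 of 16 at least 2-fold higher, 1 lower and a median below 0 after scaling to the same median and after trimmed mean scaling. FEA1, an iron-assimilating protein gene, had 11.01 RPKM in the replete and 0.318 RPKM in the deprived library (-3.19). The ferroxidase gene FOX1 had 18.2 and 8.93 RPKM (-0.95), and the cytochrome c6 gene CYC6 had 5.29 and 16.1 RPKM (1.44). Heat shock and chaperone genes had a median of 0.10 that turned below 0 under 3 of 4 scalings, with 4 of 58 at least 2-fold higher and 3 lower. The small heat shock genes HSP22F (140 and 537 RPKM) and HSP22E (169 and 560 RPKM) had log2 folds of 1.93 and 1.72, and chaperonin CPN20 had 153 and 57.6 RPKM (-1.39). Starch metabolism genes had a median of 0.23, with 2 of 27 at least 2-fold higher, namely SSS5 (1.34) and the phosphorylase PHOA (1.31), and 1 lower, the dikinase GWD2 (-1.05). Mitochondrial respiration genes had a median of 0.05, below 0 after scaling to the same median and after trimmed mean scaling, with 1 of 85 at least 2-fold higher, NUOS4b (1.03); NDA1 and AOX1 had 0.999 and 0.80. Histone genes (5 measured, median 0.13) and nucleotide and RNA recycling genes (8 measured, median 0.10) had no member 2-fold different with the pseudocount of 1 RPKM, and the histone median was below 0 after quantile normalization and the recycling median under 3 of 4 scalings. The largest absolute folds among histones were 0.81 for HON2 (0.606 and 1.81 RPKM), which was 1.43 with a pseudocount of 0.1 RPKM and 1.58 without, and 0.35 for HBV1, where HTA24 had the pattern of a gene without reads in either library, and those in the other list were 0.53, 0.51 and 0.39 for the amino acid transporters AOT5, AOT4 and AOT6.

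Other genes with the highest folds were TRP5, a transient receptor potential channel gene (2.34 and 50.3 RPKM, 3.94), and TEF13, a predicted protein gene (36.8 and 490.3 RPKM, 3.70). Other genes with the lowest folds were the adenylate kinase gene ADK4 (112 and 23.3 RPKM, -2.21), the glutaredoxin gene GRX6 (75.2 and 21.7 RPKM, -1.75), GLPX1 (108 and 34.8 RPKM, -1.61), the aspartate aminotransferase gene AST4 (30.1 and 9.18 RPKM, -1.61) and CGLD11 (21.7 and 7.18 RPKM, -1.47). All 99 named genes above the filter kept the sign of their fold under each of the 4 scalings. Most were chosen for a large fold, so this was largely built in. The scalings moved the median fold over all genes by at most 0.17. Folds of genes below a few RPKM depend on the pseudocount and on few reads. Without a pseudocount, the genes at least 2-fold higher numbered 10 in the flagellar, 8 in the heat shock and 3 in the mitochondrial list, and those at least 2-fold lower numbered 2 in the carbon-concentrating and 2 in the metal homeostasis list. With 5 RPKM, the genes at least 2-fold higher numbered 3 in the flagellar list, 2 each in the heat shock and sulfur deprivation lists, 1 each in the sensing, starch, nitrogen and fermentation lists and 0 in the phospholipid and mitochondrial lists, and no gene of the flagellar, starch, carbon-concentrating or cell wall list was at least 2-fold lower.

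Counts of list members at least 2-fold different also moved with scaling. After scaling to the same median, higher members numbered 4 in the carbon-concentrating, 3 in the flagellar, 2 in the cell cycle and 2 in the heat shock list, 1 each in the sensing, nitrogen and fermentation lists, and 0 in the phospholipid, mitochondrial and autophagy lists. Lower members numbered 7 in the heat shock list (with CPN60B1, CPN60C, CPN23 and HSP70C added), 3 in the carbon-concentrating list, 2 each in the photosystem, metal homeostasis and chlorophyll lists, and 1 each in the phospholipid and Calvin-Benson lists. PTB7 was then below 2-fold, as it was after trimmed mean scaling and quantile normalization. After scaling to a common sum, higher members numbered 9 in the carbon-concentrating, 8 in the flagellar, 7 in the cell cycle and 6 in the heat shock list. They numbered 5 in the sulfur deprivation list, 3 each in the fermentation and starch lists and 2 each in the sulfolipid and mitochondrial lists. No starch gene was then at least 2-fold lower.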

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

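The fold without pseudocount, the lists without misfitting members and the removal of genes at the shared ratio were chosen after the data were seen. Genes at least 2-fold higher numbered 775 as reported, 1277 with a pseudocount of 0.1 RPKM, 1376 with none, 286 with 5 RPKM, 513 after scaling to the same median, 512 after quantile normalization and 511 with a mean RPKM of at least 5. Genes at least 2-fold lower numbered 227 as reported, 356 without pseudocount, 115 with 5 RPKM, and 440, 397 and 395 after scaling to the same median, trimmed mean scaling and quantile normalization. Genes at least 4-fold higher numbered 143 as reported, 236 with 0.1 RPKM, 254 without pseudocount and 57 with 5 RPKM, and genes at least 4-fold lower 7, 13 with 0.1 RPKM and 17 without pseudocount. The pseudocount settings act by construction on weakly expressed genes, and the higher mean RPKM leaves fewer genes. Scaling to the same median and trimmed mean scaling apply a single factor per library that lowers the folds, so they shift these counts by construction. The cause of the shifts under quantile normalization was not tested. The other 24 counts stayed within 1.5 times the reported count. Among lists outside the random range, sensing and polyphosphate genes had 0.30 with 5 RPKM, cytosolic ribosomal proteins -0.044 after quantile normalization and -0.23 with a mean RPKM of at least 5, autophagy genes 0.35 with that filter, fermentation genes 0.47 without misfitting members and cell wall genes 0.33 without genes at the shared ratio, each then within the random range; the cause was not tested. The phosphatase median was 2.10 without misfitting members. The other 315 list values kept their side of the random range, and no list outside it changed direction. Scaling to the same median, trimmed mean scaling and scaling to a common sum shift a list and its random lists almost alike. Agreement under these scalings was therefore built in. Of the values of named genes, 58 moved by over 1.5 times, under the pseudocount settings alone, and 635 did not. Scalings with a single factor per library shift every fold by less than that limit, so they could not add to the 58. No paired analysis was possible because each condition has 1 library, and no library could be left out. At 1000 bases, about 10.4 and 12.3 reads lie behind 1 RPKM, so folds of genes near 1 RPKM rest on few reads.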

Other observations

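The scan of symbol families, the tests of plastid ribosomal protein genes and those of the shared ratio were chosen after the results were seen; the tests of scaling, of weakly read genes and of neighbouring genes were set out before, except the split of genes below 50 RPKM, which was added after. A scan covered 72 families with at least 8 measured members under a common symbol stem, and only some of those outside the central 95% are described here. Others outside it include CPLD (46 genes, median -0.20, 0 of 10000 random lists as low), SRP (-0.50), FKB (-0.32), CYN (-0.20) and SMC (0.57). Some families overlap the lists above, as the chaperonins do with the heat shock list. Translation initiation factor genes (EIF) had a median log2 fold of -0.68, with 20 of 25 below 0 and 0 of 10000 matched random lists as low. The initiation factor 3 subunit genes EIF3A (36.7 and 15.0 RPKM in the replete and deprived library, -1.24), EIF3B (60.7 and 25.3 RPKM, -1.23) and EIF3I (90.4 and 38.3 RPKM, -1.22) had the lowest folds, and the cap-binding factor gene EIF4E had -1.09. Small nuclear ribonucleoprotein genes (SMP) had a median of -0.55, with 10 of 11 below 0. Radial spoke genes (RSP) had a median of 0.61 with 15 of 15 above 0, and flagellar and basal body genes (FBB) 0.70 with 10 of 11 above 0. The medians of these 4 families kept their sign under all 4 scalings. They lie further from 0 than the scalings moved the median fold over all genes, at most 0.17, so that outcome says little. The MCM replication genes, a part of the cell cycle list picked after its values were seen and too few for the scan, had a median of 0.92 with 6 of 6 above 0. The chaperonin family (CPN) had a median of -0.88 with 8 of 9 below 0, and both sets kept these counts under all 4 scalings. For the MCM genes, whose lowest fold was 0.57, the same limit applies. CPN20 (-1.39) and CPN60A (-1.34) were the lowest of the chaperonins, and the member above 0, CPN2 (0.49), is described as a tubulin folding cofactor.

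Of the 143 genes at least 4-fold higher, 103 (72.0%) had no symbol, against 78.2% of all genes with a mean RPKM of at least 1. Outside the naming rule, Cre09.g404900 had the highest fold of the table, with 0.0688 and 345 RPKM (8.34) and a replete value within rounding of that of a gene without reads, and Cre01.g044300 had 0.228 and 107 RPKM (6.46). The scavenger receptor gene SRR22 had 5.32 and 34.4 RPKM (2.49). Genes at least 4-fold different in the same direction stood next to each other in the order of locus identifiers in 21 pairs (19 higher, 2 lower), against a median of 1 and a maximum of 7 over 10000 random placements, 0 of which gave as many. Examples are PTB3 beside PTB2, GDPD1 beside GDPD2, the run from Cre02.g144650 over PTB5 and Cre02.g144734 to PTB4, and, among lower genes, FEA1 beside Cre12.g546600 and Cre09.g403450 beside Cre09.g403500. Chance placement is thereby argued against, while shared regulation, tandem copies and reads counted for both neighbours were not tested.

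More genes were at least 2-fold higher than lower in the deprived library. The ratio of higher to lower genes was 3.41 as deposited, 1.17 after scaling to the same median and 4.99 after scaling to a common sum. Centring on the median brings this ratio towards 1 by construction, so scaling is neither shown nor excluded as the source. Among 1405 genes with a mean RPKM of at least 50 the ratio was 1.06 as deposited (86 higher and 81 lower). It was 0.444 (59 and 133) after scaling to the same median and 0.492 (60 and 122) after trimmed mean scaling. Quantile normalization gave 0.817 (76 and 93) and scaling to a common sum 1.46 (104 and 71). Among the 12450 genes below 50 RPKM it was 4.72 as deposited (689 and 146). After those scalings, in that order, it was 1.48, 1.75, 1.44 and 7.11. A high RPKM can also rest on few reads. Under the added-count reading, Cre02.g102200 (53.6 and 305 RPKM) would have about 11.1 reads in the deprived library. Noise of weakly read genes stays open too, since it needs the excess among such genes but spreads both ways, and so does a response to phosphate deprivation, which was not tested separately.

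Plastid ribosomal protein genes were lower in the deprived library. A trend of the fold with expression level is argued against, as 0 of 10000 lists matched on expression were as low. This is the list comparison already given in the results, whose outcome was known, and not a separate test. A drop of equal size in plastid and cytosolic ribosomal protein genes is argued against as well, since the plastid median lay 0.92 below the cytosolic one (difference -0.92). A smaller drop shared by ribosomal protein genes stays open. The cytosolic list was itself below the random lists (median -0.23, percentile 1.05), though not after quantile normalization or with a mean RPKM of at least 5. Of the scanned ribosomal families, RPL (42 genes, -0.27, 37 below 0, 85 of 10000 random lists as low) was low too. So were MRPS (-0.18, 176 of 10000) and MRPL (-0.14, 100 of 10000). The RPS family lay within the range (-0.21, 702 of 10000). A difference between the cultures other than phosphate cannot be told apart from the treatment with 1 library per condition. The hypothesis that phosphate deprivation lowers plastid ribosomal protein transcripts therefore remains open.

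The ratio of 0.870 between the libraries was shared by 1249 genes, 405 of them with a mean RPKM of at least 1 (2.92% of such genes). A real difference of these genes is argued against, because no other ratio was shared to 6 digits by more than 12 genes with a mean RPKM of at least 1. A fixed count added to every gene before scaling, with these genes being without reads, is a candidate explanation, since 100% of the quotients that allowed the test were whole numbers. At the 4 loci with the highest value, 160.7 RPKM in the replete library, among them LSM5, the quotient read as length would be 1 base, so what it stands for there is open. Of 144 genes at least 4-fold different that allowed the test in the replete library, 9 had such a value there, with 0.265 expected by chance matching of whole quotients. None had such a value in the deprived library. That says little, because only the 7 genes at least 4-fold lower could have one there, and no chance expectation was computed for that library.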
